A study of Homo sapiens with 20 samples.

How the data were processed

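Total RNA (20 µg per labelling) of 4 melanoma cell lines was reverse transcribed with amino-allyl dUTP and coupled to Cy dyes, per the labels' protocols. Each of the 20 arrays held 1 line in Cy5 and another in Cy3, per the labels. The titles of the 8 arrays that set a brain metastatic line against 113/6-4L write that line as 113/6-4, and the source names of the same arrays write 113/6-4L, which was used. The 4 arrays of a comparison were taken as 4 replicates. The series' design text speaks of 4 independently grown passages and of 2 technical replicates per condition with dye swap, which leaves open whether dye swaps share extracts. No 2 arrays held identical intensities.

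The scanner files hold foreground and local background intensity of 49152 spots per array on a linear scale up to 65535. These intensities were quantified from the scanned images by a histogram method, with neither background subtraction nor crosstalk correction, per the file headers of the 10 arrays that carry a header. The other 10 files have the same columns and no header, so the quantification method of these is not given in the sources used here. A deposited filter column of another kind marks spots set aside in spot finding, 1 to 336 per array, and these were treated as missing. The deposited background standard deviation column, also of another kind, was used for the planned filter alone.

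The authors' value table holds 38879 probes as natural log ratios of the first-named over the second line. Its direction is stated in the labels. Its scale was found by setting each column against the log2 ratio of the background-subtracted intensities over the brightest spots, where the slope had a median of 1.45 (range 1.43 to 1.80) against 1.44 for a natural log, and the correlation ranged from 0.63 to 1. Column medians lay between -0.007 and 0.0069. The centring method, and why some probes are listed and others not, stay unknown. On 20 of 20 arrays, a value was missing exactly where the filter column set a spot aside. The values served as an alternative.

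Spots whose names begin with hH were tested (42529 probes, all with unique names). The other 6429 named spots and the 194 empty spots were left out of the tests, and weighted 0 in the loess, on the assumption that they are controls. The sources used here do not describe the prefixes. Intensities were corrected with normexp (offset 50) and normalised within each array by global loess with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading. The log2 ratio of Cy5 over Cy3 was fitted with lmFit over all 20 arrays, with 1 coefficient for each of the 5 comparisons, signed by the dye of the first-named line, and a dye term (14 residual degrees of freedom). Moderated tests followed with eBayes (prior degrees of freedom 7.19), two-sided, adjusted by Benjamini-Hochberg over probes, with calls at an adjusted p under 0.05. All calls of the 5 comparisons also had an absolute log2 fold change of at least 1. Reported log2 ratios of a comparison are means over 4 arrays with the SD between arrays, and the dye effect cancels in them. Line differences not hybridised directly and the closure of direct and indirect ratios were contrasts of the same fit.

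The planned filter on dim probes (foreground above local background by 2 SD in 50% of a line's channels) removed 0 probes, because the local background (medians of 82 to 853) lay far below the empty spots (medians of 816 to 6825). A comparison with the 95th percentile of the empty spots of the same array and channel was therefore used to describe brightness and as an added alternative, chosen after the data were examined. Lower bounds of fold changes used intensities after loess and Aquantile normalisation.

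The rule for named genes, fixed before the data were examined, required gene symbols. Because the files do not pair probe names with genes, it was narrowed afterwards to 4 probes, as was the choice of lists to none. The 2 upward ones are those called in all 4 comparisons of a brain metastatic line. The 2 downward ones have the lowest mean log2 fold change over WM239 among probes called lower in both brain metastatic lines with that sign on all 8 arrays. The planned gene list tests (camera) and the planned named genes were not run.

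The fit was tested on simulated data with the moderated spread of each probe over 42529 probes and 200 changed probes per comparison. Of 100 probes changed by a log2 fold change of 2, it recovered 93% for 113/6-4L over WM239, 87% for 131/4-5B1 over WM239, 86% for 131/4-5B2 over WM239, 82% for 131/4-5B1 over 113/6-4L and 86% for 131/4-5B2 over 113/6-4L. Of 100 changed by a log2 fold change of 1 it recovered 11%, 13%, 5%, 13% and 8% in the same order. False calls were 7.14%, 7.41%, 3.19%, 4.04% and 6.93% of the calls. The simulated noise was independent and equally wide on every array, with reduced dye effects. The real arrays differed in spread and may share extracts, so these rates may be too favourable for them. Overlaps between comparisons that share a line were set against 100 simulations of unchanged lines with shared RNA. The simulation treats all noise as coming from the RNA of the lines and none as coming from the array.

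Alternatives covered background correction, within-array and between-array normalisation, the filter, the dye term, a model with 1 coefficient per line and arrays of 1 comparison alone. They also covered random blocks for replicate number and for the presence of a file header, a stand-in for scan batch, and averaged dye-swap pairs. The pairs were assumed to be replicates 1 with 3 and 2 with 4 of each comparison. The authors' value table and the omission of each array in turn were further alternatives. Figures were drawn with matplotlib.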

Results

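Gene expression was compared between 4 human melanoma cell lines by direct hybridisation of 2 lines at a time on 2-colour spotted oligonucleotide arrays. WM239 (WM239A in the design text) is the poorly metastatic parental line, 113/6-4L is a highly metastatic variant derived from it, and 131/4-5B1 and 131/4-5B2 are described as brain metastatic lines. The 20 arrays covered 5 comparisons with 4 arrays each, 2 in each dye orientation. Each of the brain metastatic lines was set against WM239 and against 113/6-4L, and 113/6-4L was set against WM239. The arrays carried 42529 probes that were tested, 6429 other named spots and 194 empty spots. The median Cy5 intensity of the tested probes ranged from 726 to 4796 between arrays and the median Cy3 intensity from 880 to 6970. Between 16.3% and 41.9% of the tested probes exceeded the 95th percentile of the empty spots of their array in Cy5, and between 13.1% and 41.8% did so in Cy3. Over the lines, 14514 probes (34.1%) exceeded it in at least 50% of the channels holding 1 of the lines, and these are called bright probes in what follows. The sources used here pair no probe with a gene, so differences are given by probe and no gene group was tested. The number of arrays limits the precision. The median 95% confidence interval of a comparison's log2 fold change extended 0.588 to either side over bright probes.

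The comparison of 113/6-4L with WM239 asked how the highly metastatic variant differed from its parental line. At an adjusted p under 0.05, 59 of 42529 probes differed, of which 36 were higher and 23 lower in 113/6-4L. Their median absolute log2 fold change was 1.90, and the extremes were 3.41 and -3.63. Of the 59 probes, 58 had the same direction on all 4 arrays and 56 were bright. The list depended on the processing. The omission of replicate 1 gave 38 probes, and median centring without loess gave 44 (21 higher, 23 lower). A model with 1 coefficient per line gave 275 (140 higher, 135 lower). Probe hHC009919 was lower in 113/6-4L, by a log2 ratio of -3.33 ± 1.52 (SD, n = 4 arrays; limma adjusted p = 0.000752). It exceeded the empty spots in WM239 on 4 of 4 arrays and in 113/6-4L on 0 of 4, where it was not well above background, so the difference is given as at least 4.29-fold. Such bounds set the dim line at the lowest normalised signal of any probe above the empty spots of that channel, or at the probe's own signal where that was higher, and they depend on the background correction.

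The brain metastatic line 131/4-5B1 differed from WM239 in 112 probes, 74 higher and 38 lower in 131/4-5B1. The authors' value table gave 302, 150 higher and 152 lower, the omission of background correction gave 314, and the omission of 1 of its 4 arrays gave 44 to 73. Their median absolute log2 fold change was 1.97, with extremes of 4.07 and -3.55, and 109 of them had the same direction on all 4 arrays. Line 131/4-5B2 differed from WM239 in 132 probes, 74 higher and 58 lower. That list also depended on the processing: the authors' value table gave 879 probes, 390 higher and 489 lower, the omission of background correction gave 887, and the omission of replicate 1 gave 60. Their median absolute log2 fold change was 1.88, with extremes of 4.18 and -3.98, and 127 had the same direction on all 4 arrays. Probe hHR031315 was higher in both lines, with a log2 ratio of 4.07 ± 0.575 (SD, n = 4; limma adjusted p = 1.09e-06) in 131/4-5B1 and 3.98 ± 0.858 (SD, n = 4; limma adjusted p = 1.06e-06) in 131/4-5B2. Probe hHR031258 was higher by 3.68 ± 0.957 (SD, n = 4; limma adjusted p = 2.14e-05) and 3.74 ± 0.792 (SD, n = 4; limma adjusted p = 1.64e-05). In WM239 itself, hHR031315 exceeded the empty spots on 2 of 4 arrays of either comparison and hHR031258 on 1 of 4. Probe hHC009919 was lower in both lines, by -3.52 ± 0.451 (SD, n = 4; limma adjusted p = 0.000241) and -3.98 ± 1.46 (SD, n = 4; limma adjusted p = 5.64e-05). It was not well above background in either brain metastatic line, which gives at least 6.43-fold for 131/4-5B1 and at least 8.86-fold for 131/4-5B2. Probe hHC005636 was lower by -3.03 ± 1.23 (SD, n = 4; limma adjusted p = 0.0333) and -3.79 ± 1.76 (SD, n = 4; limma adjusted p = 0.00351), and likewise was not well above background in the brain metastatic lines, which gives at least 6.69-fold and at least 6.34-fold. These sizes and bounds hold for the normexp correction. Without background correction the mean log2 fold change of both brain metastatic lines over WM239 was smaller, at 2.76 for hHR031315, 1.94 for hHR031258, -2.04 for hHC009919 and -1.74 for hHC005636, and each still passed the test.

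**Figure D1:**
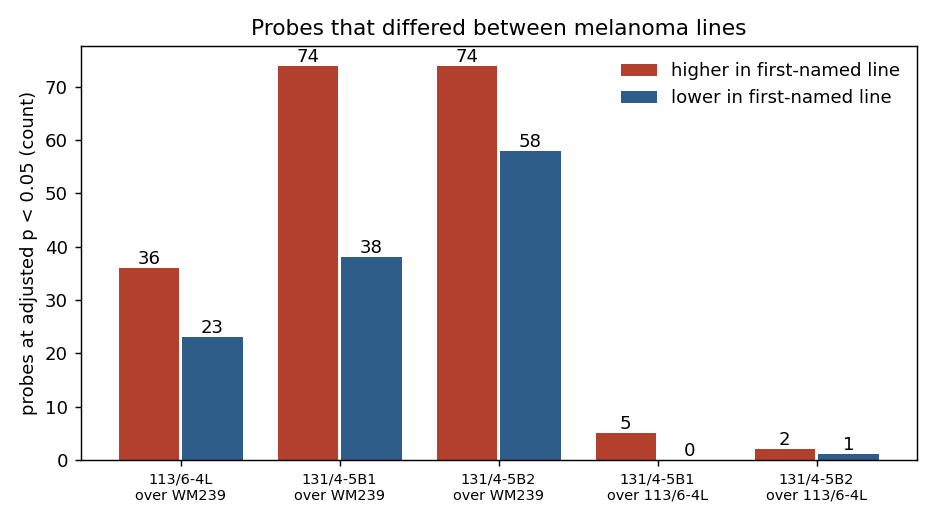
Number of probes at an adjusted p under 0.05 in each of the 5 comparisons, split by whether they were higher or lower in the first-named line. Comparisons with WM239 held 59, 112 and 132 probes, and comparisons with 113/6-4L held 5 and 3.

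Against 113/6-4L the lists were short. In 131/4-5B1, 5 probes differed, each higher than in 113/6-4L, and in 131/4-5B2, 3 probes differed, 2 higher and 1 lower. The 8 calls were bright and had the same direction on all 4 arrays of their comparison. Length and balance of these lists depended on the processing. The omission of background correction gave 29 probes (15 higher, 14 lower) for 131/4-5B1 and 38 (20 higher, 18 lower) for 131/4-5B2. A model with 1 coefficient per line gave 31 and 36. The omission of any 1 of its 4 arrays took the 131/4-5B1 list to 2. Probe hHR031315 was higher by 3.98 ± 0.981 (SD, n = 4; limma adjusted p = 4.98e-06) in 131/4-5B1 and by 3.29 ± 0.468 (SD, n = 4; limma adjusted p = 0.000147) in 131/4-5B2. In 113/6-4L it exceeded the empty spots on 1 of 4 arrays of either comparison. Probe hHR031258 was higher by 3.61 ± 1.06 (SD, n = 4; limma adjusted p = 0.000106) and 3.32 ± 0.301 (SD, n = 4; limma adjusted p = 0.000427). It was not well above background in 113/6-4L on any of these arrays, which gives at least 10.6-fold and at least 8.20-fold under the normexp correction. Without background correction the mean of both lines over 113/6-4L was 2.32 for hHR031315 and 2.20 for hHR031258, and both passed. Probes hHC009919 and hHC005636, lower against WM239, lay near background here and did not pass the test (limma adjusted p = 1 in each). hHC009919 exceeded the empty spots on 0 of 4 arrays in either line, and hHC005636 on 0 of 4 in the brain metastatic lines and on 2 and 1 of 4 in 113/6-4L, so a difference between these lines was not excluded.

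The count of unadjusted p-values under 0.05 was 3936 for 113/6-4L over WM239, 3122 for 131/4-5B1 over WM239 and 4083 for 131/4-5B2 over WM239, against 2126 expected by chance. It was 1966 for 131/4-5B1 over 113/6-4L and 1755 for 131/4-5B2 over 113/6-4L. Over bright probes alone these 2 comparisons gave 818 and 812, against 726 expected. A model with 1 coefficient per line gave 2413 and 2786 over all probes. With the mean of both brain metastatic lines as the estimate, 424 probes differed from WM239 (229 higher, 195 lower) and 44 from 113/6-4L (29 higher, 15 lower). The authors' value table turned the balance of the former to 744 higher and 913 lower, and the latter fell to 17 (14 higher, 3 lower) without replicate 2 of 131/4-5B1 over 113/6-4L and to 6, all higher, with dye-swap pairs averaged. Without background correction the latter rose to 194 (99 higher, 95 lower). The former fell to 260 without replicate 3 of 131/4-5B1 over WM239. The averaged contrasts were chosen after the data were examined.

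The design also asks which differences the brain metastatic lines had against both of the other lines. Exactly 2 probes passed in all 4 of these comparisons with the same direction, hHR031315 and hHR031258, both higher in the brain metastatic lines. Simulated unchanged lines with shared RNA gave 0 such probes in each of 100 simulations, which carries little weight because unchanged lines yield almost no calls. The product of the 4 list shares gives 7.1e-10 probes for the upward direction, but it treats the 4 comparisons as independent although they share lines. The count fell to 0 within either set of 10 arrays described further on and to 1 with pairs averaged within these sets, and it reached 42 for bright probes in a model with 1 coefficient per line. In 113/6-4L over WM239 the same probes had log2 ratios of -0.71 ± 0.296 (SD, n = 4; limma adjusted p = 0.539) and -0.33 ± 0.618 (SD, n = 4; limma adjusted p = 0.839). Neither was well above background on the arrays of that comparison.

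**Figure D2:**
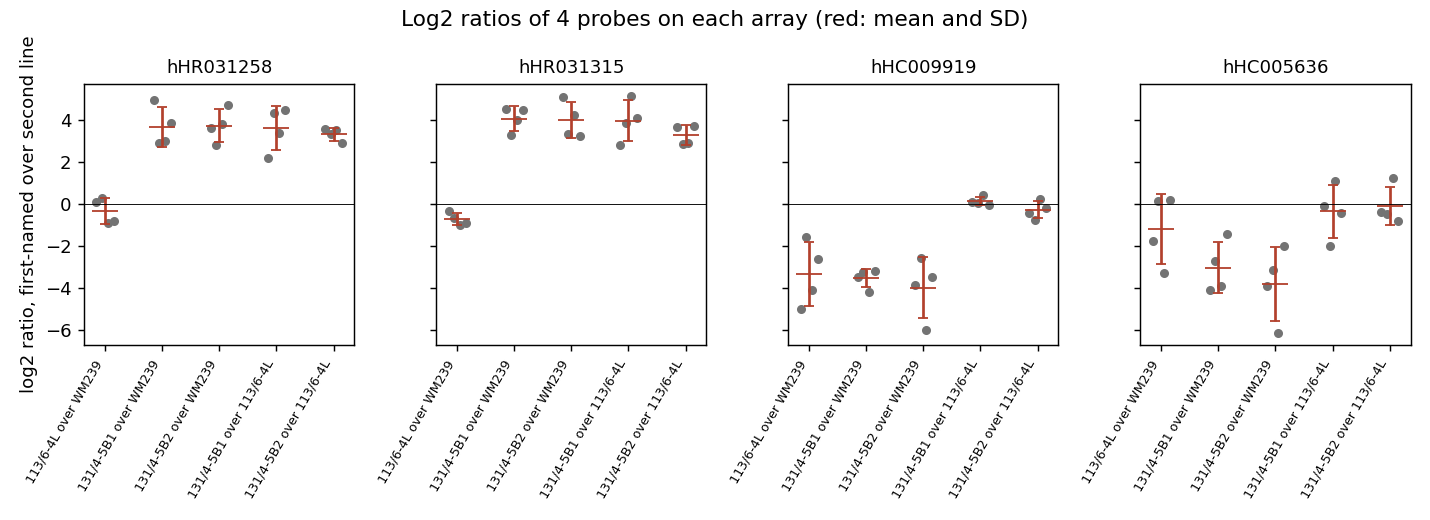
Log2 ratio of the first-named over the second line for 4 probes on each of the 20 arrays, with the mean and SD of the 4 arrays of a comparison in red. Probes hHR031258 and hHR031315 lie above 2 on every array that holds a brain metastatic line, and hHC009919 and hHC005636 lie below -1 on every array that sets a brain metastatic line against WM239.

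The calls against WM239 overlapped between the brain metastatic lines. Of the 112 and 132 probes, 68 were called in both, 42 higher and 26 lower in each line, and 0 were called in opposite directions. Both comparisons share the WM239 line, so part of the overlap may come from it. Simulated unchanged lines against a shared line gave 0 shared calls in each of 100 simulations, where almost no probe is called at all, so this value does not separate the shared line from a shared change. Independent lists of these sizes would share 0.13 probes upward and 0.052 downward. The correlation of log2 fold changes across bright probes was 0.564, against 0.50 in the simulation. Equal noise terms set that 0.50 whatever the data, so setting 0.564 against it does not test a shared change. The covariance of log2 fold changes was 0.108, against 0.0446 in the simulation. When 131/4-5B1 was taken from the 10 arrays whose files carry a header and 131/4-5B2 from the other 10, so that no array served both, the correlation was 0.295, and in the opposite assignment it was 0.491. These correlations are across probes, which are not independent replicates.

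**Figure D3:**
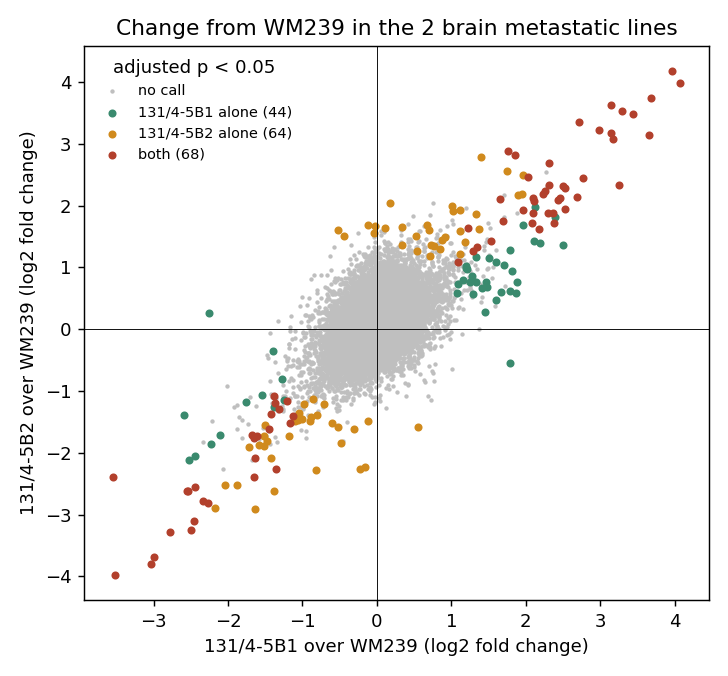
Log2 fold change over WM239 in 131/4-5B1 (horizontal) and 131/4-5B2 (vertical), 1 point per bright or called probe. Coloured points passed an adjusted p of 0.05 in 1 or both of the lines. The 68 probes called in both lie in the quadrants where both lines change the same way, and 44 and 64 probes were called in a single line.

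Calls in 113/6-4L overlapped with those in the brain metastatic lines. Of its 59 probes, 36 were also called in 131/4-5B1 (23 higher, 13 lower) and 34 in 131/4-5B2 (19 higher, 15 lower), with 0 in opposite directions. Independent lists would share 0.063 upward and 0.021 downward probes with 131/4-5B1, and 0.063 and 0.031 with 131/4-5B2. The simulation with shared WM239 RNA gave 0 in both cases, again because it yields almost no calls. The correlation of log2 fold changes with 113/6-4L across bright probes was 0.459 for 131/4-5B1 and 0.405 for 131/4-5B2. Both lay below the simulated 0.50, which equal noise terms set whatever the data, so this does not test a shared change. The covariance of log2 fold changes with 113/6-4L was 0.074 for 131/4-5B1 and 0.0775 for 131/4-5B2, against 0.0446 and 0.0448 simulated. With the 113/6-4L and brain-line values taken from opposite sets of arrays, with and without a header, it was 0.0671 and 0.0642. In all 3 derived lines 30 probes were called, all 30 in the same direction. Of the 68 probes called in both brain metastatic lines, 38 were not called in 113/6-4L, which does not show that they were unchanged there.

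The brain metastatic lines were not hybridised together, so their difference was estimated through WM239 and 113/6-4L. In limma 0 of 42529 probes passed an adjusted p of 0.05, and 1758 had an unadjusted p under 0.05, against 2126 expected. A model with 1 coefficient per line also gave 0 probes, with 1789 at an unadjusted p under 0.05. The median 95% confidence interval of this difference extended 0.588 on the log2 scale to either side over bright probes, as for a single comparison. In simulated data the fit recovered 5% to 13% of probes changed by a log2 fold change of 1 in a single comparison. Differences of that size between the brain metastatic lines were therefore not excluded, nor were smaller ones. Over the 176 probes called in either line against WM239, the median absolute difference between the lines' changes from WM239 was 0.483, with a median interval of 0.926 to either side. For 38 of the 176 the unadjusted interval excluded 0; these probes were selected by a call in 1 or both lines, which favours unequal values. Over 113/6-4L, the changes of the brain metastatic lines correlated at 0.423 across bright probes, with a covariance of 0.0356. The simulation with a shared line gave 0.50 and 0.0447, but it takes all noise as RNA noise, so values below it do not exclude a shared change. With the lines taken from opposite sets of arrays, with and without a header, no array served both. The correlation was then 0.299 or 0.217 by assignment, and the mean covariance was 0.0335. The sets may share extracts.

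Direct and indirect ratios were compared as a check of line labels and dye orientation. The change of a brain metastatic line over WM239 should equal its change over 113/6-4L plus that of 113/6-4L over WM239. In limma 0 probes departed from this for 131/4-5B1 and 0 for 131/4-5B2, with 2071 and 1990 at an unadjusted p under 0.05 against 2126 expected. The direct and the indirect change over 113/6-4L correlated at 0.301 for 131/4-5B1 and 0.309 for 131/4-5B2 across bright probes. All 5 and all 3 probes called directly had the same sign in the indirect ratio. The closure combines 3 comparisons, so its intervals are wider than those of a single comparison and the absence of calls is a weak check. The noise-corrected slope of direct on indirect change was 1.00 (SE 0.049) for 131/4-5B1 and 0.836 (SE 0.041) for 131/4-5B2. Small departures spread over many probes therefore stay open for 131/4-5B2.

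These counts depended on how the arrays were treated as replicates. The design text does not settle whether the dye swaps re-used the same extracts, and the p-values may therefore measure partly technical spread. Arrays of opposite dye orientation were therefore averaged in pairs, replicate 1 with 3 and 2 with 4 of each comparison. This pairing was assumed, as it is not known which arrays share extracts, if any. It left 27 calls for 113/6-4L over WM239, 38 for 131/4-5B1 over WM239 and 42 for 131/4-5B2 over WM239. It left 2 for 131/4-5B1 over 113/6-4L and 2 for 131/4-5B2 over 113/6-4L. The arrays also fell into 2 sets, 10 whose files carry a scanner header and 10 without, each with 1 array per dye orientation of every comparison. Within the set with headers, 131/4-5B2 over WM239 gave 66 probes, 131/4-5B1 over WM239 gave 6 and 131/4-5B1 over 113/6-4L gave 3. Within that set 113/6-4L over WM239 and 131/4-5B2 over 113/6-4L gave 0 in limma, with 3046 and 2301 at an unadjusted p under 0.05. Within the set without headers, 131/4-5B1 over WM239 gave 6 and 131/4-5B2 over WM239 gave 1. There 113/6-4L over WM239, 131/4-5B1 over 113/6-4L and 131/4-5B2 over 113/6-4L gave 0 in limma, with 3543, 1642 and 1177 at an unadjusted p under 0.05. Across bright probes the sets correlated at 0.287 for 113/6-4L over WM239, 0.486 for 131/4-5B1 over WM239, 0.365 for 131/4-5B2 over WM239, 0.226 for 131/4-5B1 over 113/6-4L and 0.318 for 131/4-5B2 over 113/6-4L. The correlation was 0.0901 for the difference between the brain metastatic lines. With a dye term of its own for each set, the counts were 58, 104, 127, 4 and 3 for the 5 comparisons in the order given.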

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

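The counts of sign-flipped splits were planned before their results were seen; the tests of the 3 patterns weighed here were chosen after related values had been seen.

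The change from WM239 differed between lines for a few probes. Between 131/4-5B1 and 113/6-4L, each over WM239, 2 probes differed at an adjusted p under 0.05, and between 131/4-5B2 and 113/6-4L also 2. For the mean of the brain metastatic lines the number was 3, each with a larger upward change than in 113/6-4L. Probe hHR031315 had a log2 difference of 4.74 (limma adjusted p = 8.06e-06) and hHR031258 of 4.04 (limma adjusted p = 0.00049) in that last test. Both values contain a ratio of 113/6-4L over WM239 measured with neither line above the empty spots, and the direct log2 fold changes over 113/6-4L were 3.63 and 3.47. Among 50 sets of 4 array values tested for an array far from the other 3, 0 had one, where chance gives about 1 in 20.

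Spots outside the tested probes carried signal. The share of spots above the 95th percentile of the empty spots in at least 50% of a line's channels was 97.6% for names beginning with hCP, 59.8% for hCT, 29.4% for hCX, 21.5% for hCM and 13.9% for hCN, against 1.55% for the empty spots themselves.

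Far more probes differed from WM239 (112 and 132 in the brain metastatic lines) than from 113/6-4L (5 and 3). A larger residual spread on the 113/6-4L arrays is argued against, since their median residual SD over bright probes was 0.866 times that of the WM239 arrays. The fit also used 1 residual variance per probe for all comparisons, with median intervals of 0.587 to 0.588 to either side over bright probes. A larger spread on some arrays would thus not have widened the intervals of their comparisons alone. Compression of the ratios as the whole cause is argued against too: it would need a noise-corrected slope of direct on indirect change of 0.569 or less, and the slopes were 1.00 (SE 0.049) for 131/4-5B1 and 0.836 (SE 0.041) for 131/4-5B2. That bound was set after the slopes were seen; a first bound of 0.8 left 131/4-5B2 undecided, since its slope was not above it by 2 standard errors, so a smaller compression in that line stays open. The covariance of log2 fold changes between the 2 sets of arrays, with and without a scanner header, was 0.0354 for the comparisons with 113/6-4L and 0.11 for those with WM239, a ratio of 0.323, consistent with the hypothesis of a biological difference in which the brain metastatic lines lie closer to 113/6-4L than to WM239; effects common to both sets raise it too, as it was 0.00422 (SE 0.0021) and 0.0109 (SE 0.0029) for the closure of 131/4-5B1 and 131/4-5B2, whose true value is 0. The 2 kinds of comparison also differed in signal level. On brain-line arrays without a header, median Cy3 intensity was 6811 to 6970 with WM239 and 1514 to 2221 with 113/6-4L. With a header it was 1739 to 2417 and 880 to 3165, which overlap. Whether this contributes to the difference in covariance was not tested. Whether the sets share extracts is not known, so differences between cultures remain open.

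Replicate 2 of 131/4-5B2 over WM239 had the largest SD of log2 ratios over bright probes (1.15, against 0.445 to 0.938 on the other arrays) and a mean correlation of 0.189 with the other arrays of its comparison, the lowest among arrays of the brain metastatic lines over WM239, though 9 other arrays of the series had a lower one. A wrong dye label is argued against, as its correlation with the mean of its own comparison was positive (0.241). So is 113/6-4L in place of a line. The slope of its log2 ratios on the difference between 113/6-4L and the line replaced would then be 0. That slope was 0.882 (SE 0.09) for 131/4-5B2 and 0.896 (SE 0.063) for WM239. For 131/4-5B1 in place of 131/4-5B2 as the cause, its correlation with the mean of 131/4-5B1 over WM239 was 0.179, against 0.377 to 0.47 for the arrays of that comparison. This does not decide the point, as the 0.241 with its own comparison also lay below that range. Such an exchange stays open. A narrower signal range is a candidate explanation. On that array 21.2% of probes exceeded the empty spots, against 32.2% to 37.3% on the 3 comparable arrays. The range itself was only slightly narrower, at 3.55 log2 units against 3.68 to 3.81. Over the 6 arrays without a header that hold WM239, the range had a rank correlation of -0.94 with the SD of log2 ratios. Its rank correlation with the mean correlation to the other arrays of a comparison was 0.83. Over all 20 arrays these were -0.76 and 0.23. The range is not the whole account, as replicate 2 of 113/6-4L over WM239 had a narrower range (2.93 against 3.55 log2 units) and a smaller SD (0.938), and replicate 2 of 131/4-5B2 over 113/6-4L had 21.3% of probes above the empty spots and an SD of 0.485. No biological explanation was tested for a single array.

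Arrays of opposite dye orientation resembled each other less (mean correlation 0.083 over bright probes) than arrays of the same orientation (0.28). Wrong dye labels are argued against, since after removal of the dye term 0 of 20 arrays correlated negatively with the rest of their comparison. A dye bias that belongs to the probe is a candidate explanation: dye coefficients fitted separately on the WM239 and the 113/6-4L comparisons correlated at 0.45, and 215 probes had a dye term at an adjusted p under 0.05. It cancels between orientations in the reported means. No biological explanation was tested here, as the design gives none.

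Sign-flipped splits of the arrays were refitted. For single comparisons 8 splits exist, too few for a share under 0.05, and in each the real split was the 1 with the largest count: 59 against at most 1 for 113/6-4L over WM239, 112 against 0 and 132 against 6 for the brain metastatic lines over WM239, and 5 and 3 against 0 over 113/6-4L. For the mean of the brain metastatic lines, 1 of 100 splits (the real one) reached 424 probes over WM239, with a highest other count of 133, and 1 of 100 reached 44 over 113/6-4L, with a highest other count of 1. For the probes shared by all 4 brain comparisons, 1 of 100 splits reached 2, with a highest other count of 0. If the arrays are independent, this speaks against no difference at all between the lines compared, since the other splits had a median count of 0. It does not test whether a difference is particular to the brain metastatic lines, as the comparisons share lines. The averaged contrasts were also chosen after the data were examined. If dye swaps share extracts, the units are pairs and far fewer splits exist, and with pairs averaged the mean over 113/6-4L fell from 44 to 6. For the difference between the brain metastatic lines, the splits exchanged the labels of these lines among arrays with the same second line instead of flipping signs. The real counts were 0 for that difference and for the closure of direct and indirect ratios. All 100 of 100 splits gave as many, which holds for any data when the real count is 0, so these splits test nothing. The highest other count was 1 in both.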

How the results depend on the processing

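Counts moved with most choices, and the cause was not tested except where stated; in the order 113/6-4L, 131/4-5B1 and 131/4-5B2 over WM239, 131/4-5B1 and 131/4-5B2 over 113/6-4L, they were 59, 112, 132, 5 and 3 as reported. The probes shared by all 4 brain comparisons numbered 2, and the mean of the brain metastatic lines gave 424 over WM239 and 44 over 113/6-4L. The difference between the brain metastatic lines and the closure of direct and indirect ratios gave 0 in limma in every alternative run for them. As reported, unadjusted p-values under 0.05 numbered 1758 for the difference, and 2071 and 1990 for the closure of 131/4-5B1 and 131/4-5B2. By chance 2126 were expected for each. Without background correction the counts were 79, 314, 887, 29 and 38, with 9 shared and 1731 and 194 for the means. Plain subtraction gave 83, 327, 859, 27 and 45, with 10 shared and 1657 and 195. The authors' value table gave 66, 302, 879, 27 and 40, with 6 shared and 1657 and 204; there 49.7% of the calls of 131/4-5B1 and 44.4% of those of 131/4-5B2 over WM239 were upward, against 74 of 112 and 74 of 132. Median centring without loess gave 44, 86, 111, 3 and 2, with 21 of the 44 upward against 36 of 59. Scale normalisation between arrays gave 39, 66, 186, 5 and 12. The model with 1 coefficient per line, which adds indirect to direct ratios, gave 275, 287, 347, 31 and 36, with 11 shared and 772 and 127. The 4 arrays of a comparison on their own gave 0 in each of the 5 and 0 shared, with 2353, 2840, 2533, 2128 and 2568 unadjusted p-values under 0.05; fewer arrays leave 2 residual degrees of freedom. The assumed dye-swap pairs averaged to 1 value gave 27, 38, 42, 2 and 2, with 2 shared and 200 and 6. Dropping the dye term changed no count by over 1.5 times, nor did a random block for the presence of a scanner header. That block stands in for a scan batch, which was not recorded in the sources used here.

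With the replicate block the counts were 58, 115, 131, 5 and 3, with 2 shared and 455 and 46. Replicate numbers did not pair the arrays: deviations of same-numbered arrays of different comparisons had a mean correlation of -0.051, against 0.016 for other pairs, and 3 of 40 pairs exceeded 0.1. The planned filters on dim probes removed 0 probes and so tested nothing. The mean over all probes of a gene, the gene list tests with their alternatives and the planned named genes were not run, as no probe is paired with a gene. Signal over background was low for most probes, as 34.1% exceeded the empty spots.

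Other alternatives were chosen after seeing the data. Restricted to bright probes, the counts were 139, 266, 446, 22 and 26, with 7 shared and 1061 and 132. The model with 1 coefficient per line on bright probes gave 715, 657, 944, 114 and 123, with 42 shared and 1718 and 284. A prior variance that follows intensity gave 138, 228, 379, 26 and 28, with 7 shared and 847 and 133. Pairs averaged within the sets with and without a header gave 25, 37, 30, 2 and 1, with 1 shared and 194 and 5. The arrays with a header alone gave 0, 6, 66, 3 and 0, with 0 shared and 132 and 8, and those without gave 0, 6, 1, 0 and 0, with 0 shared and 38 and 1; unadjusted p-values for the 5 comparisons are in the report, and 58 and 11 probes were shared at an unadjusted p under 0.05. Probes of the authors' table alone gave 47, 88, 103, 2 and 2, with 1 shared and 376 and 38. Bright probes without replicate 2 of 131/4-5B2 over WM239 gave 270, 378, 255, 30 and 28, with 8 shared and 902 and 198.

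Leaving out 1 array at a time, the ranges were 38 to 72, 44 to 140, 60 to 153, 2 to 6 and 2 to 8, with 2 to 3 shared and 260 to 460 and 17 to 46 for the means. The difference between the brain metastatic lines and the closure stayed at 0 to 0. The count for 113/6-4L over WM239 moved by over 1.5 times without its replicate 1 (38). That for 131/4-5B1 over WM239 did so without its replicates 1 (44), 2 (73), 3 (44) and 4 (53), and that for 131/4-5B2 over WM239 without its replicates 1 (60), 3 (83) and 4 (87). That for 131/4-5B1 over 113/6-4L fell to 2 without any 1 of its 4 arrays. That for 131/4-5B2 over 113/6-4L rose to 8 without replicate 2 of 131/4-5B2 over WM239 and to 5 without replicate 2 of 131/4-5B1 over WM239. The mean over WM239 gave 260 and 276 without replicates 3 and 4 of 131/4-5B1 over WM239. The mean over 113/6-4L gave 26, 17, 24 and 23 without replicates 1 to 4 of 131/4-5B1 over 113/6-4L, 21, 23, 29 and 18 without those of 131/4-5B2 over 113/6-4L, and 29 without replicate 1 of 131/4-5B2 over WM239.

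For the mean of the brain metastatic lines over WM239, the 4 named probes kept their direction and passed in all alternatives that gave this mean, among them the filters on dim probes that changed nothing: 39 for hHR031258 (log2 1.94 to 4.09) and 41 each for hHR031315 (2.76 to 4.17), hHC009919 (-4.31 to -2.04) and hHC005636 (-4.16 to -1.74). The 4 arrays of a comparison on their own give no mean over both lines. Over 113/6-4L, hHR031315 passed in all 41 (2.32 to 3.91), and hHR031258 in 38 of 39, with 3.17 and a limma adjusted p = 0.0997 on the arrays without a header (range over its alternatives 1.85e-12 to 0.0997). Probe hHR031258 had fewer alternatives because it is not in the authors' value table. The shared probes found with that table therefore cannot include it.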

Other observations

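The reproducible SD of the log2 fold change, from the covariance over bright probes between the 2 sets of arrays, with and without a scanner header, was 0.324 and 0.338 for the brain metastatic lines over WM239, 0.257 for 113/6-4L over WM239, 0.176 and 0.20 for the brain metastatic lines over 113/6-4L, and 0.104 for the difference between the brain metastatic lines. The closure of direct and indirect ratios, whose true value is 0, gave 0.0649 for 131/4-5B1 and 0.104 for 131/4-5B2, but it combines 3 comparisons and is noisier. The correlation between the sets was 0.0901 for the difference between the brain metastatic lines and 0.0132 and 0.0301 for the closure. The sets may share extracts, in which case these values include differences between cultures; averaging within sets left 37 and 30 calls for the brain metastatic lines over WM239.

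Among the 6429 named spots left out of the tests, the same model gave 55 called spots in the mean of the brain metastatic lines over WM239, each higher in those lines. It gave 0 called spots in each of the 5 comparisons and 0 in the mean over 113/6-4L, and the averaged contrast was chosen after the data were examined. Of these, 27 had names beginning with hCP and 26 with hCM. The 27 hCP spots had a median log2 fold change of 0.886 (0.774 to 1.12) and a median correlation of 0.94 with each other over the 20 arrays, and the 26 hCM spots had a median of 0.946 (0.82 to 1.03) and a correlation of 0.90. Their median over WM239 in 113/6-4L was 0.535 and 0.528, and the median of all 864 hCP and 540 hCM spots in the brain metastatic lines was 0.054 and -0.021.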
